A study of Homo sapiens with 4 samples.

How the data were processed

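Poly(A) RNA of H1 human embryonic stem cells in E8 medium was sequenced as paired-end reads on an Illumina NextSeq 500, per the labels' protocols. The samples fall into 2 groups of 2 libraries, WT and MEK5DD, by their labels. The deposited table holds 17472 genes and 4 columns of signal, here gene counts normalised by the authors. Division by 1 size factor per library was inferred from the whole multiples described below. The submitters' processing notes name Trimmomatic 0.36, STAR, featureCounts 1.5.3, DESeq2 1.26.0 and the genome build hg38, with no role or order. The strand setting of the counting and the gene annotation are not given in the sources used here.

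In each library every value was a whole multiple of the smallest value, within 0.001 of a whole number for 100% of genes. The largest departure was 8.95e-05 and 0.000121 in the WT libraries and 9.98e-05 and 6.86e-05 in the MEK5DD libraries. Values were divided by that smallest value to recover reads in all 4 libraries in the same way. In MEK5DD replicate 2 that value (0.997) is so close to 1 that an automatic check of recovered reads gives no answer, and the recovery there rests on the departure given. Recovered reads ranged from 14908486 to 17628945 per library, and the 10 most abundant genes held 7.49% to 7.76% of them. Every listed gene had at least 1 read in each library, so a gene at 0 in any library is not analysed here. A spreadsheet had turned 23 gene symbols into dates, of which 22 were tested but none is named.

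Gene types and coordinates came from GENCODE v29 (GRCh38), in which 17083 symbols (97.8%) were found. Symbols in the lists were also matched through older names.

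The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, on 15721 genes with a value of at least 10 in at least 2 libraries. Folds were taken from the log2(value + 1) scale, which understates the change of low genes. P-values are two-sided and adjusted by Benjamini and Hochberg's method over all genes tested, with a threshold of 0.05. No batch is given in the labels, and no covariate was used.

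Gene lists (28 lists, 395 genes, of which 305 were tested, 76 are not listed and 14 fell below the filter) were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists with at least 5 tested genes. Of the genes, 13 belong to more than 1 list. Camera with an estimated correlation, camera on ranks and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the few libraries rather than from the number of genes. Hardly any list could pass it here, so a high adjusted p from it does not decide against a list. Camera compares a list with all other genes, and fry tests only whether a list's own genes move on balance one way.

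The lists, the tests and the genes to name were fixed before the data were examined. Named genes were MAP2K5 and MAPK7, 10 preset genes, the 8 largest rises and 8 largest falls among called protein-coding or long noncoding genes with separate groups and a mean of at least 100, and up to 4 called members per list with the largest change. Some genes that this rule takes are not reported here, though counts and list tests include them. ACVR1B, NES, DUSP6, RRM2B, TIGAR and ATF4 fall outside that rule and were chosen after their values were seen.

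The procedure was tested on simulated data for MEK5DD against WT over 15529 genes, with 200 changed. It recovered 85.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and 9 of its 198 calls (4.55%) were unchanged genes. It called 0 of 20 unchanged lists. Genes were simulated independently, both groups had the same dispersion, and changes were placed only in genes with a mean of at least 50. The simulation therefore does not test lists of correlated genes, genes with lower means or the greater spread of the MEK5DD pair.

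Alternatives were other pseudocounts, filters, scalings and variance models, a replicate term, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. The edgeR test called 2306 genes.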

Results

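H1 is an established line of human embryonic stem cells. Poly(A) RNA was sequenced from 2 libraries of unmodified H1 cells (WT) and 2 libraries of H1 cells carrying MEK5DD, all grown in E8, a defined feeder-free medium that contains FGF2 and TGF-beta. MEK5DD is a form of MAP2K5 (MEK5) with residues changed to aspartate, per the labels; it was delivered by lentivirus and the cells were selected with puromycin. MAP2K5 is the kinase directly upstream of MAPK7 (ERK5). The WT libraries held 17628945 and 14908486 recovered reads and the MEK5DD libraries 17539654 and 15756339, over 17472 listed genes. The comparison of MEK5DD with WT asks which transcripts differ between cells carrying MEK5DD and unmodified cells. The samples include no cells given lentivirus and puromycin without MEK5DD. Effects of delivery, selection or the subline thus cannot be told apart from those of MEK5DD in any result below. RNA counts do not measure ERK5 activity.

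MAP2K5 itself was measured first. Its normalised read count was 344 and 315 in the WT libraries and 3382 and 3558 in the MEK5DD libraries, a 10.5-fold rise (log2 fold change 3.40, SE 0.08, adjusted p = 5.91e-11). Without the mean-variance trend the adjusted p was 0.00802. MAP2K5 lies at chromosome 15, 67542709 to 67807123, in GRCh38. Gene-level counts cannot separate transcripts of the introduced sequence from those of the native gene. MAPK7, the substrate of MAP2K5, had a log2 fold change of 0.15 (SE 0.10, adjusted p = 0.398).

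**Figure D1:**
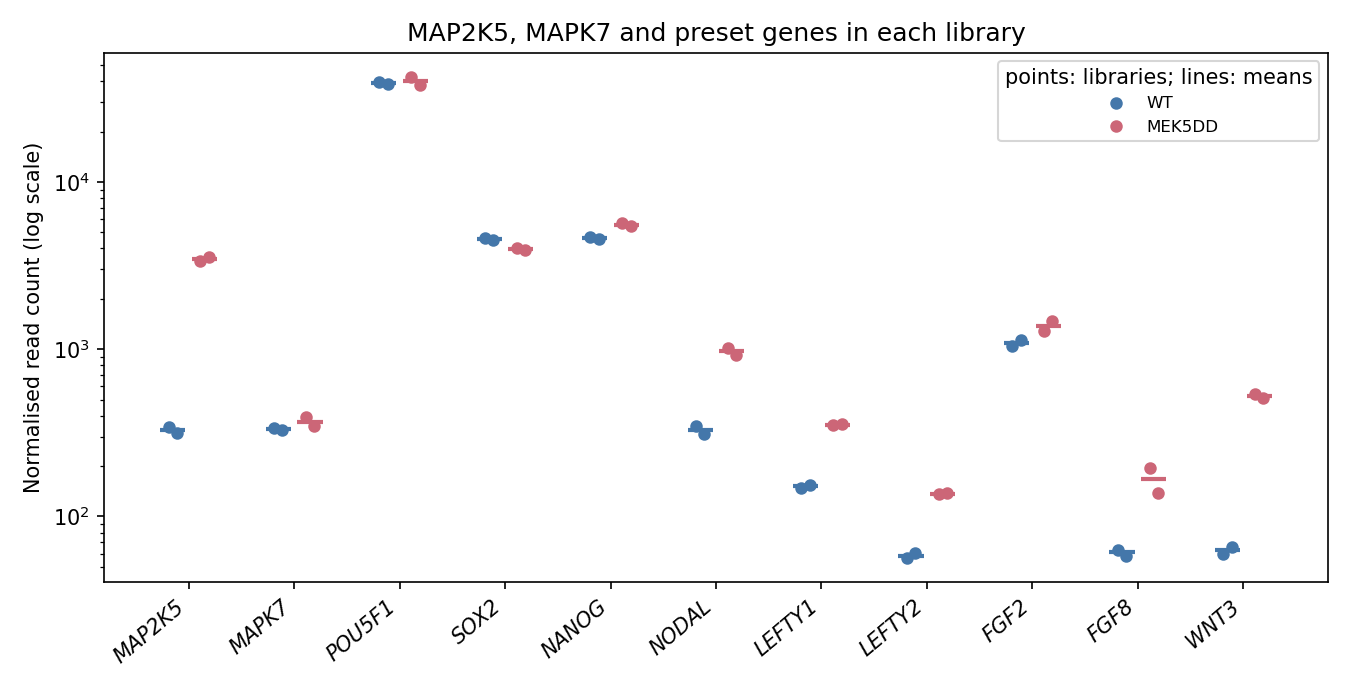
Normalised read count (log scale) of MAP2K5, MAPK7 and 9 genes chosen before the data were examined, with 1 point per library and a line at the mean of each group of 2 (blue, WT; red, MEK5DD). MAP2K5 lies at 344 and 315 in WT and at 3382 and 3558 in MEK5DD, and WNT3 and NODAL also separate upward.

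The largest rises in MEK5DD cells included the WNT ligand gene WNT3 (8.26-fold), the small GTPase gene RHOB (12.4-fold) and the neuronal microtubule regulator gene STMN2 (14.3-fold). NODAL and its feedback inhibitor genes LEFTY1 and LEFTY2 rose 2.94-fold, 2.32-fold and 2.32-fold. Several transcription factor genes of early neural tissue fell, among them SIX6 (6.60-fold lower), SOX21 (4.85-fold lower) and SOX14 (4.44-fold lower). POU5F1, the central pluripotency factor gene, stayed near its WT level (mean 39142 ± 810 in WT and 40251 ± 3019 in MEK5DD, SD, n = 2 each).

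Of 15721 genes tested with limma, 2226 passed an adjusted p of 0.05, 1209 higher and 1017 lower in MEK5DD, and 383 of them changed at least 2-fold (207 higher, 176 lower). In all 2226 the 2 WT values lay on one side of the 2 MEK5DD values, an arrangement that chance gives to 33.3% of genes and that 8832 of the tested genes showed. The MEK5DD libraries differed from each other more than the WT libraries did: the chi-square per degree of freedom was 6.11 for the MEK5DD pair and 1.88 for the WT pair, against 12.6 to 16.3 for pairs across the groups. With upper-quartile factors 1184 were higher and 1230 lower, and at 2-fold the balance turned without MEK5DD replicate 1 (229 higher, 251 lower) and without MEK5DD replicate 2 (245 higher, 277 lower). The count moved with the library left out, to 1196 without WT replicate 1, 1160 without WT replicate 2, 3743 without MEK5DD replicate 1 and 4629 without MEK5DD replicate 2, and 867 genes passed in the same direction in each of these 4 fits. Of the 95 called genes named by the preset rule, MAP2K5 left out, 49 lost their call without the mean-variance trend and 18 with DESeq2. The count was 439 without the mean-variance trend and 1358 with DESeq2, and the 2-fold count was 253 without the trend and 217 among genes with a mean of at least 50. The labels do not say whether replicates came from separate cultures and describe 1 MEK5DD line, so the p-values measure the spread between these libraries, which may be technical.

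The 8 largest rises among protein-coding and long noncoding genes of GENCODE v29 with a mean count of at least 100 were HHLA1 (log2 fold change 3.95, SE 0.10), ABHD12B (3.89, SE 0.08), STMN2 (3.84, SE 0.10), RHOB (3.64, SE 0.08), RBM46 (3.44, SE 0.12), MAP2K5, WNT3 (3.05, SE 0.13) and the metallothionein gene MT1H (2.89, SE 0.20). The 8 largest falls among the same genes were SIX6 (-2.72, SE 0.09), SOX21 (-2.28, SE 0.14), SOX14 (-2.15, SE 0.14), LOXL3 (-2.07, SE 0.13), FBP1 (-1.93, SE 0.21), SLITRK3 (-1.80, SE 0.14), SORBS2 (-1.71, SE 0.12) and SOX21-AS1 (-1.60, SE 0.16). FBP1, which encodes a gluconeogenic phosphatase, was the 1 gene among these whose call was lost without the mean-variance trend (adjusted p = 0.0614). HHLA1, ABHD12B, SIX6, LOXL3 and FBP1 overlap other listed genes, and whether counting used strand is not given in the sources used here, so part of their reads may belong to the neighbour. MT1H shares sequence with other metallothionein genes.

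Genes of the NODAL and activin pathway, which maintains pluripotency and drives mesendoderm formation, rose as a list. Of 17 tested members 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.19 (camera, adjusted p = 0.00136; adjusted p = 0.335 with an estimated correlation). NODAL rose from 329 ± 25.2 to 969 ± 73.2 (SD, n = 2 each; adjusted p = 7.72e-07 from limma). LEFTY1 and LEFTY2 each rose by 1.21 (log2), and because they are near-identical paralogs their reads may be shared. TGFB1 rose by 0.84. The receptor gene ACVR1B was the member that fell (-0.31), with an adjusted p of 0.203 without WT replicate 1 and 0.234 without WT replicate 2. NODAL and TGFB1 also overlap other listed genes.

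Among FGF ligand genes, 3 of 10 rose and 2 fell (4 and 3 adjusted over the list alone), and the list as a whole was not called (median 0.12, camera adjusted p = 0.780). FGF8 rose 2.67-fold (log2 1.42, SE 0.19) and FGF4 rose 1.86-fold, and FGF12 fell by 0.85 on the log2 scale. The call of FGF8 was lost without the mean-variance trend (adjusted p = 0.0544). FGF2 rose by 0.35 (SE 0.08), a call lost without WT replicate 1 (adjusted p = 0.207) and without the trend (adjusted p = 0.182). Of the 5 WNT ligand genes tested, WNT3 rose and WNT5A fell (-0.90, SE 0.09), with 3 higher and 1 lower adjusted over the list alone (median 0.48, camera adjusted p = 0.208). Fry called that list higher (adjusted p = 0.0277). The WNT ligand list was called higher without WT replicate 1 (adjusted p = 0.000904), without WT replicate 2 (adjusted p = 0.000182) and with DESeq2 (adjusted p = 0.0106), against adjusted p = 0.629 over all 4 libraries with an estimated correlation. Of 7 WNT target genes 0 rose and 2 fell (0 and 2 adjusted over the list alone; median -0.17, camera adjusted p = 0.179). These were the feedback inhibitor genes NKD1 (-0.52) and AXIN2 (-0.31), whose adjusted p without WT replicate 2 were 0.0544 and 0.324, and AXIN2 was also lost without WT replicate 1 (adjusted p = 0.257) and with DESeq2 (adjusted p = 0.189). Without the trend both were lost (NKD1, adjusted p = 0.0732; AXIN2, adjusted p = 0.136).

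ERK1/2 output and feedback genes moved both ways: 5 of 17 rose and 5 fell, with the same counts adjusted over the list alone (median 0.03, mean -0.05, camera adjusted p = 0.952, lower). The dual-specificity phosphatase gene DUSP5 rose by 0.74 (SE 0.07), and DUSP4, of the same family, fell by 1.03 on the log2 scale (SE 0.10). These 2 were the calls of the list that passed in every fit that left out 1 library; the other 8 were lost without WT replicate 1 and without WT replicate 2, among them DUSP6 (-0.33, adjusted p = 0.0898 and 0.0755). Immediate early genes rose as a list, with 5 of 13 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.000418; adjusted p = 0.335 with an estimated correlation). KLF6 (2.08, SE 0.07), JUN (1.36, SE 0.12) and ATF3 (0.61, SE 0.10) rose, and EGR1, which responds to growth factor signalling, fell (-1.67, SE 0.26). The calls of ATF3 and EGR1 were lost without the mean-variance trend (adjusted p = 0.0544 and 0.0512).

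The list of ERK5, MEF2 and KLF genes, which holds genes linked to ERK5 such as transcription factors and kinases, had 4 of 13 members higher and 0 lower, also adjusted over the list alone (median 0.30, camera adjusted p = 0.00162; adjusted p = 0.335 with an estimated correlation). KLF6 and KLF5 (1.17, SE 0.21) rose in every fit that left out 1 library. KLF4 rose by 0.74, with an adjusted p of 0.0850, 0.0515 and 0.136 without WT replicate 1, WT replicate 2 and MEK5DD replicate 1. MEF2D rose by 0.30, with an adjusted p of 0.372 and 0.210 without WT replicate 1 and WT replicate 2. KLF4 and MEF2D were also lost without the mean-variance trend (adjusted p = 0.103 and 0.139) and with DESeq2 (adjusted p = 0.138 and 0.173). KLF2 is not listed in the table and was not analysed here. KLF6 and NR4A1 also belong to the immediate early list, so the results of these lists are not independent.

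Among pluripotency genes 3 of 18 rose and 2 fell (5 and 2 adjusted over the list alone), and the list was not called (median -0.05, mean 0.09, camera adjusted p = 0.625, higher). DPPA2 rose by 1.51 (SE 0.10) and UTF1 by 0.56 (SE 0.07). NANOG rose by 0.26 (SE 0.06, adjusted p = 0.0117) and SOX2 fell by 0.20 on the log2 scale (SE 0.06, adjusted p = 0.0437). Both calls were lost without WT replicate 1 (adjusted p = 0.167 and 0.485) and without WT replicate 2 (adjusted p = 0.262 and 0.350). Without the mean-variance trend the calls of UTF1, NANOG, SOX2 and TFCP2L1 were lost, with an adjusted p from 0.0561 (UTF1) to 0.238 (SOX2), and with DESeq2 that of SOX2 was lost (adjusted p = 0.0990). POU5F1 had a log2 fold change of 0.04 (SE 0.06, adjusted p = 0.752), which was -0.04 without MEK5DD replicate 1 and passed the threshold without MEK5DD replicate 2 (adjusted p = 0.0062). Naive pluripotency markers, genes of the pre-implantation state, had 3 of 7 members higher and 0 lower, also adjusted over the list alone (median 0.74, camera adjusted p = 0.0237; adjusted p = 0.462 with an estimated correlation). TFCP2L1 (0.57, SE 0.10), KLF5 and KLF4 were those members, and KLF4 and KLF5 also belong to the ERK5 list. The naive list was not called without WT replicate 1 (adjusted p = 0.0685), MEK5DD replicate 1 (adjusted p = 0.232) or MEK5DD replicate 2 (adjusted p = 0.157), nor with DESeq2 (adjusted p = 0.0911).

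Neuroectoderm markers fell as a list, with 7 of 11 lower and 1 higher (7 and 2 adjusted over the list alone; median -0.85, camera adjusted p = 2.15e-05; adjusted p = 0.335 with an estimated correlation). SIX6 fell from 1277 ± 7.28 to 193 ± 8.92 (SD, n = 2 each; adjusted p = 2.06e-09 from limma). SOX1 (-2.41, SE 0.32), the neuronal microtubule protein gene MAP2 (-2.13, SE 0.32) and SOX3 (-1.32, SE 0.10) also fell, and all 7 falls passed in every fit that left out 1 library. NES, an intermediate filament gene of neural progenitors, rose by 0.35, with an adjusted p of 0.0738 without WT replicate 1.

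Primitive streak and mesoderm markers had 2 of 7 members higher and 1 lower (3 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 0.179). KDR, a VEGF receptor gene, rose by 1.02 (SE 0.06) and MIXL1 by 0.98 (SE 0.15). LHX1 fell (-1.65) from a mean of 24.4, with an adjusted p of 0.253 without WT replicate 1 and 0.0868 without MEK5DD replicate 2. The list was called higher without WT replicate 1, MEK5DD replicate 1 or MEK5DD replicate 2 (adjusted p = 0.0163, 0.0193 and 0.0138), and with DESeq2 (adjusted p = 0.0145), against adjusted p = 0.629 over all 4 libraries with an estimated correlation. Of 6 definitive endoderm markers 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.52, camera adjusted p = 0.312). Fry called the endoderm list lower (adjusted p = 0.0189). FOXA1 fell by 2.26 on the log2 scale (SE 0.34) and HHEX by 0.69. HHEX had an adjusted p of 0.0547 without WT replicate 2. GATA4 rose from 4.37 to 15.6, and its adjusted p was 0.202, 0.0790 and 0.110 without WT replicate 1, WT replicate 2 and MEK5DD replicate 1. Amnion and trophoblast markers had 1 of 6 higher, GATA3 (1.73, SE 0.39), and 3 lower, led by IGFBP3 (-1.29, SE 0.23) and GABRP (-0.94, SE 0.13), with 2 and 3 adjusted over the list alone (median -0.51, camera adjusted p = 0.286). KRT7 was the other fall (-0.85), lost without WT replicate 1 (adjusted p = 0.225). Only 4 neural crest markers were tested, too few for the list test, and ETS1 rose by 0.73 and SOX9 fell by 0.54 on the log2 scale (1 and 1 adjusted over the list alone). SOX9 had an adjusted p of 0.394 without WT replicate 2. Without the mean-variance trend the calls of MIXL1, LHX1, HHEX, GATA3, GABRP, KRT7 and SOX9 were lost, with an adjusted p from 0.0511 (GABRP) to 0.189 (SOX9). With DESeq2 those of HHEX (adjusted p = 0.0587), KRT7 (adjusted p = 0.119) and SOX9 (adjusted p = 0.0993) were lost, and LHX1 and GATA4 had no adjusted p.

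BMP target genes had 3 of 10 higher and 2 lower (4 and 2 adjusted over the list alone; median 0.16, camera adjusted p = 0.559), among them BAMBI (0.67, SE 0.09), higher, and ID2 (-0.53, SE 0.07), lower. Of 13 epithelial junction genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 0.0840). The keratin genes KRT8 and KRT18, which overlap, rose by 0.61 and 0.62. The epithelial list was called higher without MEK5DD replicate 1 (adjusted p = 0.0391), without MEK5DD replicate 2 (adjusted p = 7.70e-05) and with DESeq2 (adjusted p = 0.0234), against adjusted p = 0.629 over all 4 libraries with an estimated correlation. Mesenchymal genes had 4 of 8 higher and 2 lower (4 and 3 adjusted over the list alone; median 0.11, camera adjusted p = 0.483), and the list was called higher without WT replicate 2 (adjusted p = 0.0464; adjusted p = 0.731 over all 4 libraries with an estimated correlation). The intermediate filament gene VIM rose 2.91-fold and the transcription factor gene SNAI1 2.02-fold, and the fibronectin gene FN1 fell by 0.52 on the log2 scale. Fibroblast and feeder markers had 3 of 6 higher and 0 lower (3 and 1 adjusted over the list alone; median 0.37, camera adjusted p = 0.0463; adjusted p = 0.477 with an estimated correlation). TAGLN (1.02, SE 0.09), COL1A2 (0.75, SE 0.08) and COL1A1 (0.64, SE 0.10) rose. The fibroblast list was not called among genes with a mean of at least 50 (adjusted p = 0.0753), after quantile normalisation (adjusted p = 0.0652) or with the rank-based test (adjusted p = 0.317). Without WT replicate 1 the calls of SMAD6 (0.48, adjusted p = 0.0952) and the junction gene OCLN (-0.32, adjusted p = 0.249) were lost, as they were with DESeq2 (adjusted p = 0.0547 and 0.111). Without the mean-variance trend the calls of ID2, SMAD6, KRT8, KRT18, OCLN, FN1 and COL1A1 were lost, with an adjusted p from 0.0530 (KRT8) to 0.133 (OCLN).

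Target genes of p53 rose as a list, with 8 of 14 higher and 0 lower, also adjusted over the list alone (median 0.30, camera adjusted p = 1.04e-05; adjusted p = 0.335 with an estimated correlation). The stress cytokine gene GDF15 (1.45, SE 0.13), the cell cycle inhibitor gene CDKN1A (1.15, SE 0.08) and the pro-apoptotic gene BBC3 (0.97, SE 0.10) rose in every fit that left out 1 library. The other 5 calls were lost without WT replicate 1, with an adjusted p from 0.0612 (SESN2) to 0.383 (RRM2B), and RRM2B (adjusted p = 0.0993) and TIGAR (adjusted p = 0.303) also without WT replicate 2. Of 18 cell cycle genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; median -0.09, camera adjusted p = 0.208), and the list was called lower without MEK5DD replicate 1 (adjusted p = 0.0439; adjusted p = 0.629 over all 4 libraries with an estimated correlation). CCND3 rose by 0.54 (SE 0.10), and the proliferation marker gene MKI67 fell by 0.37 on the log2 scale (SE 0.10); the other 5 calls of the list were lost without WT replicate 1, among them MCM2 (-0.35, adjusted p = 0.0891). Unfolded protein and amino acid stress genes had 6 of 14 higher and 0 lower (6 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.0840). VLDLR rose by 0.49 (SE 0.08), the 1 call of that list that passed in every fit that left out 1 library; the other 5 were lost without WT replicate 1 or WT replicate 2, with ATF4 at an adjusted p of 0.212 and 0.322. The stress list was called higher without MEK5DD replicate 2 (adjusted p = 0.0183; adjusted p = 0.629 over all 4 libraries with an estimated correlation). Without the mean-variance trend the calls of CCND3, MKI67 and VLDLR were lost (adjusted p = 0.0774, 0.261 and 0.0732), as were those of MCM2 (adjusted p = 0.128) and SESN2 (adjusted p = 0.0909), and with DESeq2 that of MKI67 (adjusted p = 0.277).

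Of 14 glycolysis and hypoxia genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; median 0.08, camera adjusted p = 0.539), with rises of NDRG1 (1.11, SE 0.14), PDK1 (0.76, SE 0.09) and PFKP (0.47, SE 0.07). The calls of PDK1 and PFKP were lost without the mean-variance trend (adjusted p = 0.0577 and 0.0832), as was that of IRF7 (adjusted p = 0.0579). Of 14 cholesterol synthesis genes 2 rose and 1 fell, also adjusted over the list alone (median -0.03, mean 0.05, camera adjusted p = 0.952, higher). The synthesis enzyme genes SC5D (-0.32) and LSS (0.22) were among them, with an adjusted p of 0.0868 and 0.309 without WT replicate 1, 0.157 and 0.433 without WT replicate 2, and 0.132 and 0.213 without the trend. LSS was also lost with DESeq2 (adjusted p = 0.116), after quantile normalisation (adjusted p = 0.0735) and with upper-quartile factors (adjusted p = 0.0584). Of 8 interferon response genes 1 rose, IRF7 (0.85, SE 0.17), and 0 fell, also adjusted over the list alone (median 0.20, camera adjusted p = 0.286). With limma 0 of 13 mitochondrially encoded genes (median 0.04, camera adjusted p = 0.559) and 0 of 22 ribosomal protein genes (median 0.05, camera adjusted p = 0.327) passed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 mitochondrially encoded and 0 ribosomal protein genes were higher; edgeR called 1 and 0 of them, and DESeq2 0 and 0. The ribosomal list was called higher without MEK5DD replicate 2 (adjusted p = 1.68e-05) and pointed lower without MEK5DD replicate 1 (adjusted p = 0.137). Its adjusted p was 0.930 over all 4 libraries with an estimated correlation, which was 0.975 for this list. Genes of the 20q11 segment, which is often gained in cultured stem cells, had 2 of 13 higher and 2 lower, also adjusted over the list alone (median -0.00, mean 0.02, camera adjusted p = 0.952, lower). Calls of the glycolysis and 20q11 lists other than NDRG1, PDK1, PFKP and ID1 were lost without WT replicate 1, with an adjusted p from 0.0649 (HK2) upward, and ID1 was lost without the trend (adjusted p = 0.149). Of 9 imprinted genes 0 rose and 1 fell, also adjusted over the list alone (median -0.08, camera adjusted p = 0.559), PEG10 (-0.22), whose adjusted p was 0.324 without WT replicate 1, 0.376 without WT replicate 2, 0.219 without the trend and 0.0568 with DESeq2.

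**Figure D2:**
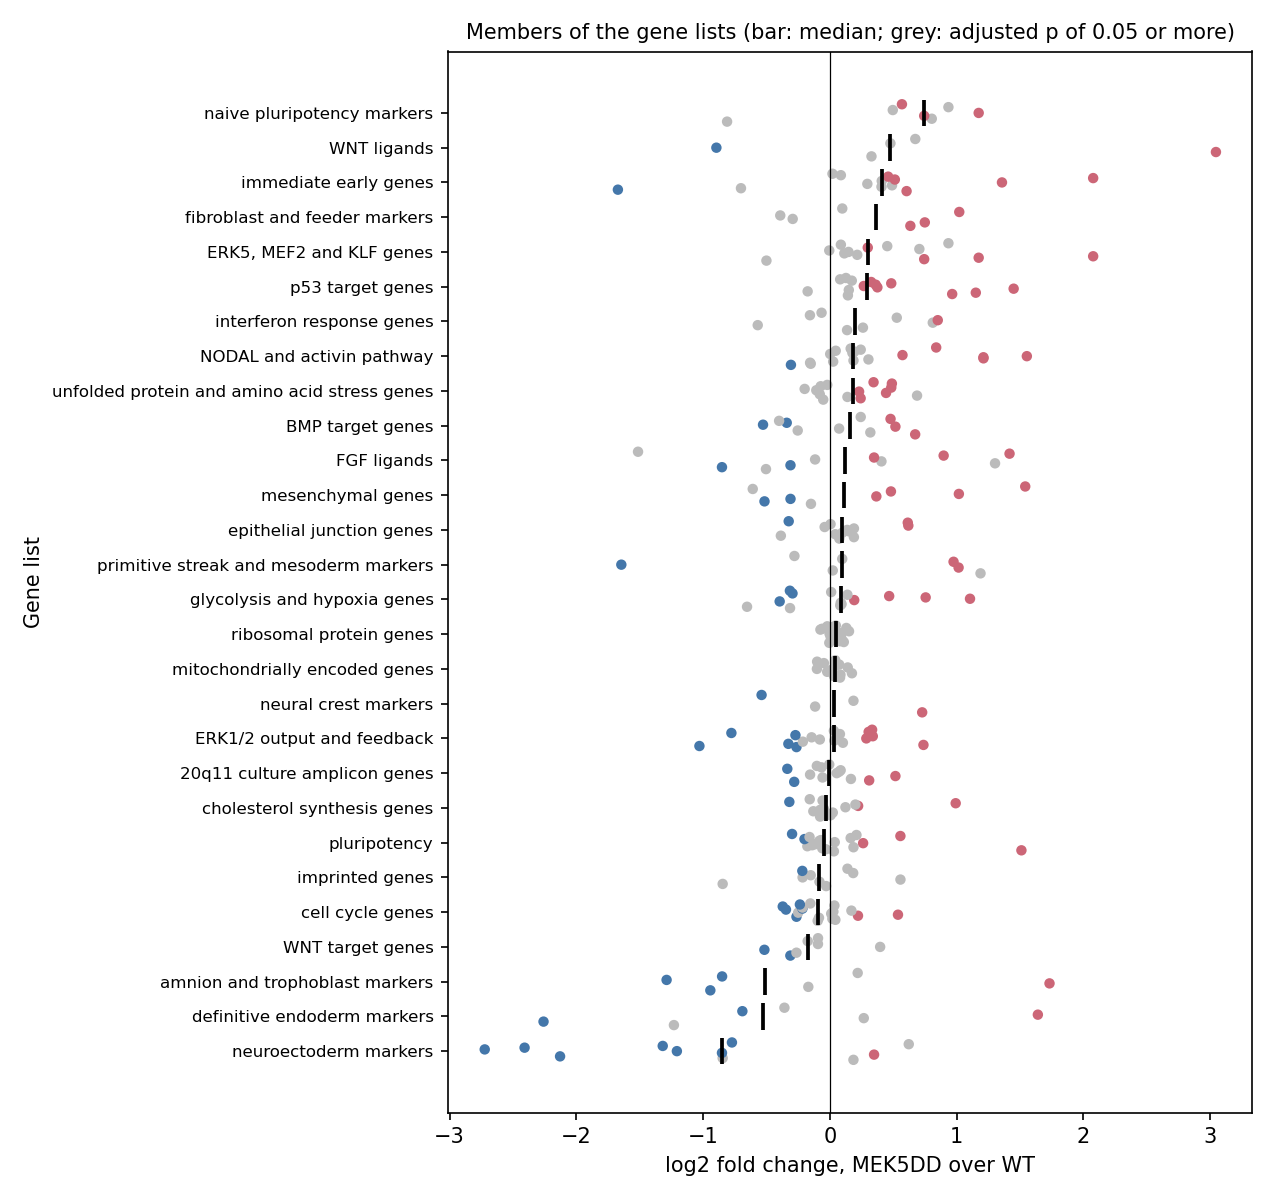
Log2 fold change of MEK5DD over WT for each tested member of the 28 gene lists, with 1 point per gene and a bar at the median of each list. Red and blue points passed the test over all genes, grey points did not. The neuroectoderm list has its median at -0.85 and the naive list at 0.74.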

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

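None of the alternatives here was chosen after seeing the results. None of the 2226 calls had the opposite sign under the 16 alternatives to the gene test. Without the mean-variance trend 439 genes passed and 253 changed at least 2-fold; with a mean of at least 50 the 2-fold count was 217, from fewer tested genes (12219). DESeq2 called 1358, all shared with the main calls (1524 adjusted p missing), and edgeR called 2306, 2224 of them shared. The 2 replicate numbers do not mark pairs in the labels (correlation of deviations 0.12 over 10787 genes). A replicate block gave 3349 genes and 9 lists. By camera it lost the naive list (adjusted p = 0.0689) and added the WNT ligand, mesoderm and epithelial lists (adjusted p = 0.0103, 0.0267 and 0.0267). Leaving out 1 library gave 1160 to 4629 genes, 343 to 522 at 2-fold, a MAP2K5 log2 fold change of 3.33 to 3.46, and 8 to 10 lists; the lone library is then assumed to vary like the remaining pair, and the WT pair varies less than the MEK5DD pair. With an estimated correlation 0 of 27 lists passed (3 at an unadjusted p under 0.05), against 6 by ranks and 9 by fry. Of the 7 lists called in the main test, fry kept all and ranks kept all but the fibroblast list. The estimated correlation of each of the 7 lists called in the main test was negative (-0.082 to -0.012), below the preset 0.01. Correlation within those lists, as estimated, therefore does not account for the loss. With an estimated correlation camera takes its degrees of freedom from the few libraries, and with the preset one from the number of genes. Fewer degrees of freedom raise the p-values, so the loss does not decide against those lists. POU5F1 reversed to -0.038 without MEK5DD replicate 1; the cause was not tested. Of 95 called named genes, 46 kept their call without the trend, 77 with DESeq2, 70 and 72 without WT replicate 1 and 2, and 92 and 94 without MEK5DD replicate 1 and 2. Those 95 leave out MAP2K5. Depth limits genes with few reads, such as GATA4 (means 4.37 and 15.6), for which DESeq2 gave no adjusted p.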

Other observations

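The gene groups below and the tests of HERV-H linked transcripts, of another subline and of non-neural markers were chosen after the results were seen; the tests of early neural genes and of chromosome segments were written before theirs. Genes of caveolae, annexins and their partners, which shape and scaffold the plasma membrane, rose in 14 of 15 tested members (median log2 fold change 1.45). ANXA1 rose 7.95-fold, LGALS1 3.96-fold, CAV1 3.59-fold, AHNAK 2.88-fold and ANXA2 2.74-fold, and CAVIN3 (0.50) was lost without WT replicate 2 (adjusted p = 0.0631). ANXA5 was the member not called (0.13, adjusted p = 0.286). The calls of S100A6, ANXA3 and CAVIN3 were lost without the mean-variance trend (adjusted p = 0.0908, 0.0512 and 0.0888). Metallothionein genes, which bind metal ions, rose in 7 of 8 tested members, led by MT1M (3.04), MT1H (2.89) and MT1E (2.32), though these paralogs can share reads; MT1L (1.36) was lost without WT replicate 2 (adjusted p = 0.241) and without MEK5DD replicate 1 (adjusted p = 0.0787), and without the trend MT1L (adjusted p = 0.112) and MT1F (adjusted p = 0.0837) were lost.

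SOXB genes, transcription factors of neural progenitors and stem cells, fell in 5 of 5 members, from SOX1 (-2.41) to SOX2 (-0.20, a call lost without WT replicate 1, adjusted p = 0.485, and without WT replicate 2, adjusted p = 0.350). SLITRK genes, which encode neuronal membrane proteins, fell in 3 of 4, of which SLITRK1 was lost without WT replicate 1 (adjusted p = 0.0847). Without the trend SOX2 (adjusted p = 0.238) and SLITRK1 (adjusted p = 0.0817) were lost, and with DESeq2 SOX2 (adjusted p = 0.0990). The WNT inhibitor gene SFRP1 fell from 4869 to 1755 and the hormone gene APELA from 676 to 294 (means, n = 2 each), and DLL3, a Notch ligand gene, rose from 210 to 818. Of the other single genes examined, LMX1B (2.15) and DACT1 (1.95) rose and LRAT (-1.12) fell. The largest fold among all genes tested was that of AC105243.1 (53.1-fold, from 22.8 to 1264), a symbol that GENCODE v29 does not hold.

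Transcripts linked, as background, to HERV-H endogenous retroviral elements were among the largest rises: HHLA1, ABHD12B, LINC00458 (2.62), ERVH48-1 (2.43), LINC-ROR (2.27) and LINC01108 (2.23). These 6 were picked because they rose, so the median of 5 others (0.0068, SD 0.68) cannot say how widely such transcripts rose. A part played by reads shared among copies cannot be told apart from a rise of some of them. Over all 11 tested, 8 rose and 0 fell, with a median of 2.23. The 6 picked rises are among these 8 and set that median, so neither figure measures such transcripts as a group. Of the 5 others CALB1 (1.30) and C4orf51 (0.88, lost without WT replicate 1 and with DESeq2, adjusted p = 0.153) rose. ESRG (-0.06, SE 0.06), SCGB3A2 (0.01, SE 0.08) and KLKB1 (-0.25, SE 0.13) were not called, which argues against a rise of every such transcript. A difference between sublines that MEK5DD did not cause cannot be told apart from its effect, because the labels describe 1 MEK5DD line.

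The fall of neuroectoderm markers may be part of a lower level of early neural genes beyond that list, though not of all of them. In a separate list of 42 early neural genes, 17 were tested, 8 fell and 0 rose, with a median of -0.34. SOX11 (0.08), NNAT (0.16) and FABP7 (0.78, SE 0.54) pointed higher without being called. Outside both lists the neuronal gene STMN2 was called higher (14.3-fold). Among 10000 random lists matched on mean expression, 0% had a median as low. Those lists hold unrelated genes, so this share does not cover genes that move together or the spread between cultures. LHX5, POU3F4 and HES3 (-0.78) passed in every fit that left out 1 library, and the other 5 falls were lost without WT replicate 1 or WT replicate 2 (ZIC2, adjusted p = 0.166 and 0.307) and also without the trend (adjusted p from 0.0732 for ZIC4 to 0.244 for PTPRZ1); whether fewer cells or less expression per cell lies behind them was not measured. A smaller share of differentiated cells of any lineage cannot be told apart from this: the median of 37 non-neural markers was 0.023 (SE 0.19), and its lower 95% bound of -0.35 reaches the -0.3 set for that explanation, though not the -0.85 of the neuroectoderm list. A second measure, tried after that result was known, was not used to decide: 9 of the 21 called markers fell (42.9%, exact 95% interval 21.8% to 66.0%), and undifferentiated cells also express several of them. The SE, the bound and the interval treat genes of the same libraries as independent and do not measure the spread between cultures.

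A gained or lost chromosome or large segment could change many genes between lines. Among 318 runs of 60 neighbouring genes (10590 genes), the median farthest from 0 was 0.16, on chromosome 19 from 52064466 to 55487568, within the bound of 0.2 set in advance for no such change. Shorter segments and gains in a small share of cells stay open.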
